A study of Mus musculus with 10 samples.

How the data were processed

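RNA was measured on 10 Affymetrix arrays, each hybridised with material labelled as cortical astrocytes from mice 8 weeks of age. Per the labels' protocols, the cells were sorted by FACS on an EGFP reporter expressed in astrocytes, their RNA was amplified as cDNA with an Affymetrix whole-transcript kit, and the cDNA was fragmented and labelled with biotin. Per the series' design text, the authors compared control with Fmr1 KO arrays in GeneSpring 13.1.1. The methods of background correction, normalization and probe set summary are not given in the sources used here. The values the authors deposited are log2 signal levels per probe set. That scale was read from the values, which ran from 4.31 to 13.9 on the arrays without centring per probe set, with medians per array between 6.11 and 6.24.

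The labels place 5 arrays in the wild-type control group and 5 in the Fmr1 KO group. The titles call the replicates biological, and whether each came from a separate animal or a pool is not stated, so p-values measure the spread between these samples. The arrays' number limits the precision. Of 33793 probe sets, 23521 have 1 gene symbol in the platform annotation, 1814 have several and 8458 have none listed. Of those with 1 symbol, 23328 were found by gene ID in a table of current symbols for assembly GRCm38.p6, and 0 had another symbol there. Probe sets with several symbols or none were left out of the comparison. For each gene the probe set with the highest mean over all arrays was kept, which mattered for 1082 genes, and probe sets with a mean below the 25th percentile of all probe sets (log2 level 5.32) were left out. This left 17712 genes.

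Differences are the mean of the arrays labelled Fmr1 KO minus the control mean on the log2 scale. They were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists for astrocyte functions, FMRP-bound mRNAs, other cell types that an EGFP gate could let through, dissociation stress, time of day, glucocorticoids and sex were written before the data were examined, as were the design and most alternatives. Of 31 lists, 30 had at least 5 measured members and were tested with camera of limma at a preset correlation of 0.01 between genes, two-sided, adjusted over the lists. The erythroid list had 2 measured members, and list members outside the 17712 genes were not analysed here. Camera with an estimated correlation, the directional test of fry, and an exact two-sided permutation test of the list means over the 252 assignments of arrays to groups, whose smallest possible p is 0.00794, were run beside it. Lists share members. For example, 19 of the 40 genes fixed for astrocyte identity and 1 of the 30 fixed for microglia and macrophages are in another list as well.

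The genes named are Fmr1, 9 astrocyte genes chosen whatever their values (Slc1a2, Slc1a3, Glul, Grm5, Kcnj10, Aqp4, Gfap, Aldh1l1 and Gja1), and in each list up to 4 measured members with the smallest unadjusted p. The rule also takes the 10 genes with the largest change per direction among those past the threshold or, since fewer than 10 passed, the 10 per direction with the smallest unadjusted p, as values only. Predicted genes, small RNA genes and olfactory and vomeronasal receptor genes were counted and not named. On simulated data with the means and spread of these 17712 genes and independent noise, the gene test recovered 31 of 50 genes changed by 1.5-fold, 47 of 50 changed by 2-fold, 49 of 50 changed by 3-fold and 50 of 50 changed by 4-fold, and called 9 of 17512 unchanged genes. All changed genes were placed in the same simulated data, and many true changes ease the Benjamini-Hochberg threshold. The recovered counts therefore do not give the power for data where few genes change. The set test recovered the 1 shifted list and called 0 of 22 unshifted lists that share no member with it. The simulation holds no correlation between genes, so it does not show how often the set test calls lists by chance on these arrays.

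Alternatives were quantile normalization or a shift to equal medians on top of the deposited values, other filters on dim probe sets, the mean of a gene's probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, other thresholds, all probe sets, and leaving out each array in turn. After the data were seen, further alternatives were added: leaving out the control arrays with Xist signal, Xist signal as a covariate, the mean of the microglia and macrophage markers as a covariate with and without those arrays, and leaving out the 3 arrays on the positive side of the first principal component.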

Results

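Expression was measured in cells sorted from mouse cortex as astrocytes, the glial cells that take up glutamate and potassium around synapses. The arrays also read microglia markers and the choroid plexus gene Ttr at high levels, as given below. Of the 10 arrays, 5 were labelled wild-type control and 5 were labelled Fmr1 KO. Fmr1 encodes FMRP, an RNA-binding protein that represses translation and whose loss causes fragile X syndrome. The study's stated comparison was control against Fmr1 KO. Correlations between arrays, across the 17712 genes tested, ran from 0.903 to 0.990, where genes are not independent replicates.

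Fmr1 signal was not lower in the arrays labelled Fmr1 KO. Its log2 level was 8.22 ± 0.15 (SD, n = 5) in them and 8.04 ± 0.26 (SD, n = 5) in controls. The KO-labelled arrays 1 to 5 read 8.32, 8.38, 8.26, 8.15 and 8.01, and the control arrays 1 to 5 read 8.28, 7.60, 8.03, 8.17 and 8.10. The difference of 0.19 ± 0.13 (SE; 95% interval -0.09 to 0.46) did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.704). It was 0.08 without control array 2 and 0.04 without control arrays 2 and 3, an alternative added after the data were seen. The annotation pairs 1 probe set with Fmr1 alone, and the sources used here do not say which part of the gene was disrupted. The signal therefore checks the labels only if its probes read that part, and the group is called "labelled Fmr1 KO" throughout. Of the 20 X-chromosomal neighbours of Fmr1 fixed beforehand, 14 were measured, 6 with a higher and 8 with a lower mean in the arrays labelled Fmr1 KO, and the list was not called (camera adjusted p = 0.831). Its median difference was -0.03 and its mean difference 0.01, so the signs differ. Cd99l2, which read 6.84 on control array 2 and 7.29 to 7.40 on the other controls, differed by 0.38 ± 0.19 (SE), Mtmr1 by 0.24 ± 0.15, Mamld1 by -0.22 ± 0.10 and Ids by -0.24 ± 0.13 on the log2 scale, with an adjusted p of 0.654 or higher for each.

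The arrays differed in sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, read 10.60 and 10.98 on control arrays 2 and 3 and between 4.98 and 5.23 on the other 8 arrays. The Y-linked genes showed the reverse: Uty read 4.82 and 4.77 on those control arrays and 7.64 to 8.30 elsewhere, and Kdm5d read 4.86 and 4.83 against 7.05 to 7.76. This is the pattern of female cells on control arrays 2 and 3 and of male cells on the other 8 arrays, although the labels give no sex. The arrays labelled Fmr1 KO were thus all Xist-low, and 3 of the 5 controls were. Sex as read from these genes was therefore not balanced between the groups. The sex-linked list as a whole, with 7 measured members, was not called (camera adjusted p = 0.831), and its median of -0.09 and mean of 0.09 differ in sign. It holds genes that move in opposite directions between the sexes, so this directional test cannot weigh a difference in sex. Ddx3x, an X-linked RNA helicase, differed by -0.33 ± 0.12 (SE), Xist by -2.26 ± 1.15, Uty by 1.30 ± 0.64 and Kdm5d by 1.07 ± 0.50, none past the threshold.

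The arrays also differed in markers of microglia, the resident immune cells of the brain. The mean of the 29 measured microglia and macrophage markers was 9.33 on control array 1 and between 10.0 and 10.2 on the other controls. It was 9.21 and 8.66 on KO-labelled arrays 1 and 2, and 9.67 to 9.90 on KO-labelled arrays 3 to 5. The mean of the 38 measured astrocyte identity genes was 10.2 on control array 1 and 9.43 to 9.82 on the other controls, against 10.6 on both KO-labelled arrays 1 and 2 and 9.62 to 9.86 on arrays 3 to 5. The same 3 arrays lay on the positive side of the first principal component, which held 48.5% of the variance, with scores of 16.3, 31.0 and 45.2, while the other arrays lay between -23.0 and -7.92. Over the 5 controls the microglia mean was 9.96 and the astrocyte mean 9.72, so the sorted material did not read as astrocytes alone. Levels of different probe sets give no shares of cells.

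**Figure D1:**
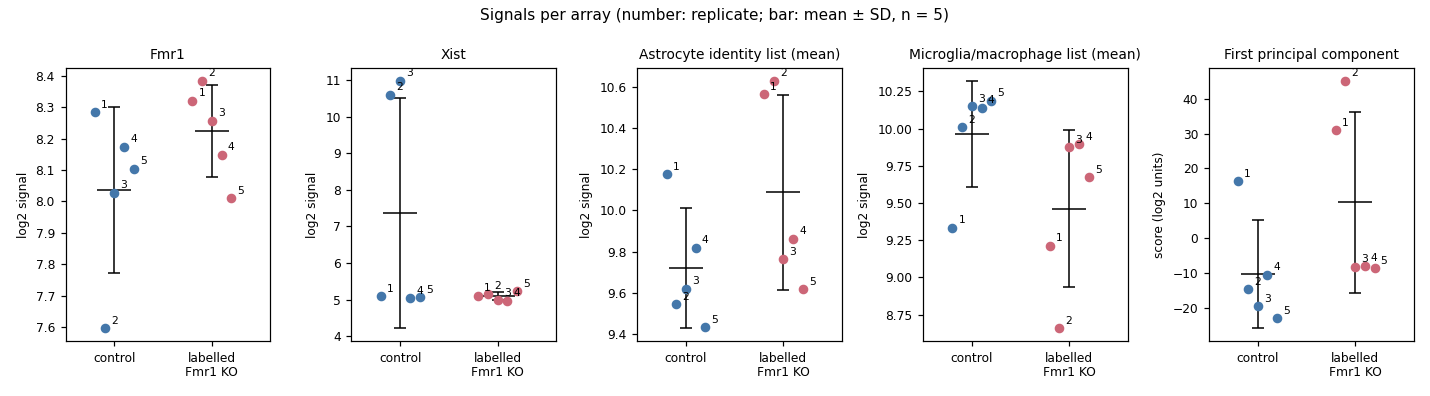
Log2 levels of Fmr1 and Xist, log2 means of the astrocyte identity and the microglia and macrophage lists, and first principal component scores, for each array by group, with replicate numbers beside the points and bars for mean ± SD (n = 5 per group). Fmr1 lay between 7.60 and 8.38 on all arrays, and Xist was high on control arrays 2 and 3 alone.

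No gene passed the threshold between the groups. The smallest p on the higher side belonged to Slc47a1, a transporter that exports organic cations, which read 7.85 ± 0.23 (SD, n = 5) on the arrays labelled Fmr1 KO and 7.19 ± 0.24 (SD, n = 5) on controls. On the lower side it belonged to the ribosomal protein gene Rpl35, at 8.50 ± 0.12 and 8.96 ± 0.11 (SD, n = 5 each). Their differences were 0.66 ± 0.14 (SE) and -0.46 ± 0.09 (SE), seen in 5 of 5 KO-labelled arrays against the control mean, with a limma adjusted p of 0.654 for both. The other genes of the 10 with the smallest p on the higher side were Zfhx2, Selenbp1, Akap6, Unc13c, Ccr7, Dcc, D4Ertd617e, Gucy1a2 and Epb41l4b. Among them Akap6, which anchors protein kinase A, differed by 0.72 ± 0.18 (SE), Unc13c, a vesicle priming protein, by 0.71 ± 0.18, and the netrin receptor Dcc by 0.84 ± 0.22. The lower side also held Cnbd2 at -0.62 ± 0.12 (SE), Prr15l at -0.31 ± 0.07 and 7 more ribosomal protein genes or their pseudogenes. Those were Rps12 at -0.55 ± 0.11, Rpl34-ps2 at -0.32 ± 0.07, Rps28 at -0.50 ± 0.11, Rps4x at -0.57 ± 0.13, Fau at -0.58 ± 0.13, Rps6 at -0.54 ± 0.13 and Rpl13 at -0.45 ± 0.11. Such genes have near-identical copies in the genome, so single values among them are uncertain.

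In numbers, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.654. At an unadjusted p under 0.05 there were 1334 genes, 709 higher and 625 lower, where chance gives 886 on average. Other splits of the same arrays, described below, gave a median of 521 and up to 3788. The side with more genes depended on the arrays: without KO-labelled array 5 there were 1129 higher and 499 lower, without KO-labelled array 1 343 and 462, without control array 1 1171 and 1256, without control arrays 2 and 3 288 and 433, and with array weights 696 and 753. The unadjusted count was 2427 without control array 1, 805 and 794 without KO-labelled arrays 1 and 2, and 721 without control arrays 2 and 3, with 0 genes past the adjusted threshold in each of these. Groups did not overlap for 171 genes, or 0.965%, where chance gives 0.794%. Leaving out control array 5 put 1 gene past the threshold, Cnbd2 at -0.74 (adjusted p = 0.0237, in a range of 0.0237 to 0.973 over its alternatives), and Cnbd2 read 7.96 on that array and 8.49 to 8.60 on the other controls.

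Astrocyte identity genes had higher means in the arrays labelled Fmr1 KO. Of 38 measured, 37 had a higher and 1 a lower mean, with a median difference of 0.39, and the list was called (camera in limma, Benjamini-Hochberg adjusted p = 1.5e-11; adjusted p = 0.524 with an estimated correlation). The bicarbonate transporter Slc4a4 differed by 0.54 ± 0.18 (SE), Itih3 by 0.55 ± 0.20 and the glutamate transporter Slc1a2 by 0.47 ± 0.18, while Cst3, which encodes cystatin C, differed by -0.33 ± 0.12. At an unadjusted p under 0.05 there were 8 higher members and 1 lower, and 0 passed adjusted over all genes or adjusted over the list alone. The median was 0.26 without KO-labelled array 1 and 0.25 without KO-labelled array 2, with the call kept in both. The same count holds for every list reported here: 0 members passed adjusted over all genes and 0 adjusted over the list alone. The microglia markers, lower in the same arrays, moved opposite to this list and to the astrocyte function lists that follow.

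Of the 9 astrocyte genes chosen by name, Slc1a2 read 11.5 ± 0.25 (SD, n = 5) on the arrays labelled Fmr1 KO and 11.1 ± 0.40 (SD, n = 5) on controls. The second glutamate transporter Slc1a3 differed by 0.44 ± 0.20 (SE), the potassium channel Kcnj10 by 0.39 ± 0.22, the water channel Aqp4 by 0.45 ± 0.27, Aldh1l1 by 0.38 ± 0.21, the gap junction gene Gja1 by 0.31 ± 0.27, Gfap by 0.21 ± 0.20 and glutamine synthetase, Glul, by 0.10 ± 0.14. The glutamate receptor Grm5, read by the arrays at 5.32 ± 0.11 and 5.31 ± 0.23 (SD, n = 5 each), differed by 0.01 ± 0.11 (SE). These levels lie at the cutoff of 5.32 for dim probe sets, so they do not show that Grm5 was unchanged. Grm5 was kept in 16 of 23 alternatives. None of the 9 genes passed the threshold (limma adjusted p = 0.654 or higher for each).

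Lists for transport around the synapse had higher medians. In the potassium, water and gap junction list 13 of 15 measured members had a higher mean, with a median of 0.42 (camera adjusted p = 4.98e-05; adjusted p = 0.524 with an estimated correlation), among them Dtna at 0.57 ± 0.19 (SE), the chloride channel Clcn2 at 0.48 ± 0.17 and Gjb2 at 0.22 ± 0.10. In the GABA list 12 of 14 had a higher mean, with a median of 0.35 (camera adjusted p = 6.19e-04; adjusted p = 0.524 with an estimated correlation). The GABA transaminase Abat differed by 0.51 ± 0.20 (SE), the receptor subunits Gabbr2 by 0.56 ± 0.22 and Gabrb1 by 0.62 ± 0.27, and the GABA-making enzyme Gad1, a low signal at 5.76 on controls, by -0.24 ± 0.10. In the glutamate list 13 of 17 had a higher mean, with a median of 0.21 (camera adjusted p = 0.0137; adjusted p = 0.647 with an estimated correlation). The glutamate receptor Grm3 differed by 0.55 ± 0.24 (SE) and the glutamine transporter Slc38a3 by 0.46 ± 0.22. In the calcium and G-protein receptor list 14 of 18 had a higher mean, with a median of 0.14 (camera adjusted p = 0.0185; adjusted p = 0.524 with an estimated correlation), and Plcb1 differed by 0.55 ± 0.20 (SE), Ntsr2 by 0.29 ± 0.15 and Atp2b2 by 0.29 ± 0.16. Without KO-labelled array 2 the medians were 0.25 for the potassium list, 0.19 for GABA, 0.07 for glutamate and 0.06 for calcium, and without KO-labelled array 1 the potassium median was 0.27. The glutamate median was 0.31 without control array 1, 0.13 without control array 3 and 0.34 without KO-labelled array 5. The glutamate call ended without control array 2, 3 or 5 or KO-labelled array 1 or 2 (camera adjusted p = 0.0648 to 0.0828), and the calcium call without control array 2 or 5 (0.0865 and 0.0624). Without control arrays 2 and 3 together, the calls for the GABA, glutamate and calcium lists ended at adjusted p = 0.0613, 0.366 and 0.105, with GABA and glutamate medians of 0.18 and 0.06.

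Genes for contact with synapses showed the same sign. Of 23 measured members of the synapse engulfment and cell contact list, 18 had a higher mean, with a median of 0.36 (camera adjusted p = 1.46e-04; adjusted p = 0.524 with an estimated correlation). The adhesion molecule Ncam1 differed by 0.58 ± 0.16 (SE), Ephb1 by 0.40 ± 0.15, Ncan by 0.49 ± 0.19 and Nrcam by 0.54 ± 0.23. Of 27 secreted factors that act on synapses, 21 had a higher mean, with a median of 0.24 (camera adjusted p = 1.59e-04; adjusted p = 0.524 with an estimated correlation), among them Bmp7 at 0.45 ± 0.13 (SE), the thrombospondins Thbs3 at 0.24 ± 0.09 and Thbs4 at 0.27 ± 0.13, and the glypican Gpc5 at 0.56 ± 0.24. The contact list's median was 0.19 without KO-labelled array 2. Without control arrays 2 and 3 it was 0.23 and its call ended (camera adjusted p = 0.0525), and the secreted factors' median was 0.13 with the call kept.

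Among metabolic lists, 20 of 21 members of the cholesterol synthesis list had a higher mean, with a median of 0.17 (camera adjusted p = 0.00573; adjusted p = 0.71 with an estimated correlation). Fads2, a fatty acid desaturase and not itself a cholesterol enzyme, differed by 0.61 ± 0.22 (SE). Nsdhl differed by 0.41 ± 0.24, Srebf2 by 0.31 ± 0.21 and Ebp by -0.28 ± 0.12. At an unadjusted p under 0.05 in limma the list held 1 higher member, Fads2, and 1 lower, Ebp. Of 23 genes of lipid transport and fatty acid oxidation, 18 had a higher mean, with a median of 0.16 (camera adjusted p = 0.0120; adjusted p = 0.647 with an estimated correlation). In that list the lysosomal cholesterol carrier Npc2 differed by -0.38 ± 0.11 (SE), Abcg4 by 0.36 ± 0.16, Clu by 0.26 ± 0.14 and Apoe by 0.33 ± 0.18. The cholesterol call ended without control array 5 or KO-labelled array 1 or 2 (camera adjusted p = 0.0600 to 0.168), the lipid call without control array 2 or KO-labelled array 1 or 2 (0.0584 to 0.0975), and both without control arrays 2 and 3 (0.278 and 0.467). The cholesterol median was 0.08 without control array 5 and 0.10 and 0.06 without KO-labelled arrays 1 and 2, against 0.31 without control array 1 and 0.32 without KO-labelled array 5. The lipid median was 0.08 without KO-labelled array 1 and also 0.08 without array 2, against 0.24 without control array 1 and 0.26 without KO-labelled array 5, and 0.08 without control arrays 2 and 3. Glycolysis and lactate genes, 17 higher and 9 lower, were not called (camera adjusted p = 0.341), but they were called higher without KO-labelled array 5 (median 0.18, 0.0299) and lower with the microglia marker mean as a covariate and without control arrays 2 and 3 (-0.18, 1.23e-05). Aldoc differed by 0.48 ± 0.20 (SE), Pygb by 0.44 ± 0.19, the lactate transporter Slc16a7 by -0.48 ± 0.20 and Pgam1 by -0.33 ± 0.16. Oxidative phosphorylation genes, 15 higher and 25 lower, were not called either (camera adjusted p = 0.320), with Ndufa1 at -0.59 ± 0.21 (SE), but they were called lower without control arrays 2 and 3 (median -0.11, adjusted p = 0.00732) and without control array 3 or 5 or KO-labelled array 1 or 2 (0.00261 to 0.0346).

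**Figure D2:**
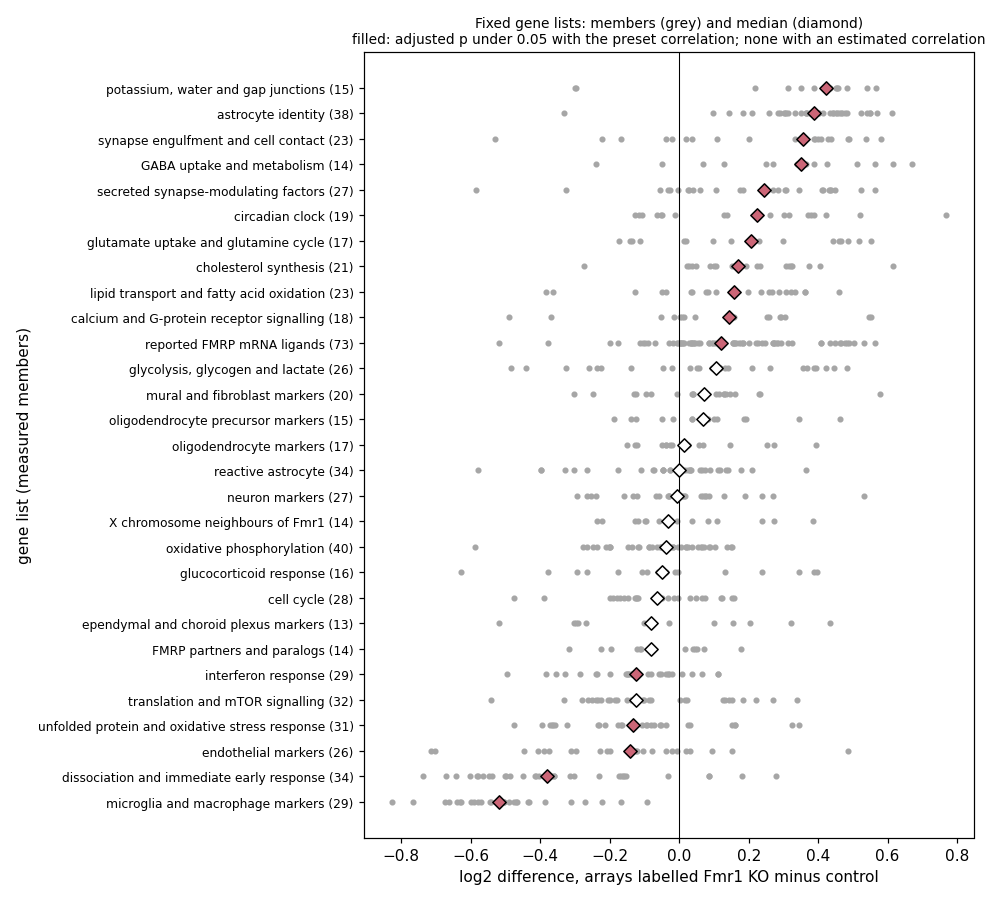
Median log2 difference (arrays labelled Fmr1 KO minus control) of each tested gene list except the sex-linked list, as diamonds over grey points for the single measured members, filled where camera at the preset correlation gave an adjusted p under 0.05 (none with an estimated correlation). The medians ran from -0.52 for microglia and macrophage markers to 0.42 for potassium, water and gap junction genes.

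Reported FMRP mRNA ligands were a list fixed from knowledge of the protein's bound transcripts. Of 73 measured, 60 had a higher and 13 a lower mean in the arrays labelled Fmr1 KO, with a median of 0.12 (camera adjusted p = 3.84e-08; adjusted p = 0.524 with an estimated correlation). Their mean log2 level was 8.09 ± 0.07 (SD, n = 5) against 7.94 ± 0.10 (SD, n = 5) in controls, and the exact permutation p of 0.0317 became 0.492 after adjustment over the lists. The list mean was 8.18 and 8.13 on KO-labelled arrays 1 and 2 and 8.07 on control array 1, the arrays with the lowest microglia marker means, against 8.00 to 8.06 on the other KO-labelled arrays and 7.80 to 7.99 on the other controls. Of the 80 genes fixed, 15 are in another list as well. The transcription factor gene Zfhx2 differed by 0.45 ± 0.10 (SE), the cytoskeletal linker Macf1 by 0.28 ± 0.08, the sodium channel Scn8a by 0.49 ± 0.15 and the phosphodiesterase Pde2a by -0.52 ± 0.17. At an unadjusted p under 0.05 there were 17 higher members and 1 lower. The call of reported FMRP mRNA ligands was kept without control arrays 2 and 3 (median 0.07, camera adjusted p = 0.00228), and with the microglia marker mean as a covariate as well (median 0.05, camera adjusted p = 0.0197). FMRP partners and paralogs, 6 higher and 8 lower, were not called (camera adjusted p = 0.303), with Mov10 at -0.32 ± 0.14 (SE), Ncl at -0.22 ± 0.11, Pum2 at -0.20 ± 0.13 and Cyfip2 at 0.18 ± 0.16. Translation and mTOR genes, 11 higher and 21 lower, were not called (camera adjusted p = 0.136), with the initiation factors Eif4g3 at 0.27 ± 0.09 (SE) and Eif4g2 at -0.23 ± 0.09, the elongation factor Eef1a1 at -0.28 ± 0.10 and Pik3cb at -0.54 ± 0.24. Without control arrays 2 and 3 both were called lower, at medians of -0.15 each (camera adjusted p = 0.00228 and 0.00761), and so they were without control array 2 alone (0.00854 and 0.0190).

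Microglia and endothelial markers had lower means, and markers of other cell types were not called with all arrays. All 29 measured microglia and macrophage markers had a lower mean in the arrays labelled Fmr1 KO, with a median of -0.52 (camera adjusted p = 1.5e-11; adjusted p = 0.524 with an estimated correlation). The receptor Gpr34 differed by -0.83 ± 0.28 (SE), Tyrobp by -0.77 ± 0.32, Trem2 by -0.60 ± 0.25 and Tmem119 by -0.64 ± 0.26. The median was -0.29 without KO-labelled array 2. Control array 1 lay below the other controls in the list mean, in Tyrobp (8.70 against 9.55 to 9.86) and in Tmem119 (8.25 against 9.17 to 9.43). Of 26 endothelial markers, 21 had a lower mean, with a median of -0.14 (camera adjusted p = 1.17e-04; adjusted p = 0.524 with an estimated correlation). Their mean log2 level was 6.92 ± 0.07 (SD, n = 5) against 7.09 ± 0.11 (SD, n = 5), and the exact permutation p of 0.0238 became 0.492 after adjustment. The VEGF receptor Flt1 differed by -0.45 ± 0.13 (SE), the tight junction gene Cldn5 by -0.41 ± 0.13, Ptprb by -0.38 ± 0.12 and Emcn by -0.23 ± 0.08. These are low signals: on the arrays labelled Fmr1 KO they read 6.54, 5.93, 6.15 and 5.77, where probe sets below 5.32 were left out as dim. The endothelial median was -0.22 without control arrays 2 and 3. Mural and fibroblast markers, 13 higher and 7 lower, were not called (camera adjusted p = 0.177), with Pdgfrb at 0.58 ± 0.24 (SE), Anpep at 0.23 ± 0.11, Notch3 at 0.15 ± 0.08 and Cnn1 at -0.25 ± 0.11, but they were called higher with array weights (0.0233), without control array 1 (0.0288), without KO-labelled array 2 (0.0474) and without control array 1 and KO-labelled arrays 1 and 2 together (0.0291). Cnn1 was a low signal, at 5.71 on controls.

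Neuron markers, 13 higher and 14 lower, were not called (camera adjusted p = 0.950), and their median of -0.01 and mean of 0.00 differ in sign. Map2 differed by 0.53 ± 0.24 (SE), Vsnl1 by 0.24 ± 0.12 and Stmn2 by -0.29 ± 0.12, the last 2 from low signals of 6.01 and 6.21 on controls. Oligodendrocyte markers, 9 higher and 8 lower (camera adjusted p = 0.807), and oligodendrocyte precursor markers, 10 higher and 5 lower (0.263), were not called, with Plekhb1 at 0.39 ± 0.25 (SE), Aspa at 0.25 ± 0.17, Olig2 at 0.46 ± 0.23 and Bmp4 at 0.35 ± 0.18. On the lower side were Fa2h at -0.13 ± 0.08 (SE), Nkx6-2 at -0.15 ± 0.12, Neu4 at -0.14 ± 0.10 and C1ql1 at -0.19 ± 0.14. Ependymal and choroid plexus markers, 5 higher and 8 lower, were not called (camera adjusted p = 0.868), but they were called lower with Xist signal as a covariate (median -0.16, 0.0476) and with the microglia marker mean as a covariate and without control arrays 2 and 3 (-0.28, 0.0111). Dynlrb2 differed by 0.43 ± 0.13 (SE), Ak7 by 0.32 ± 0.21, Otx2 by -0.52 ± 0.27 and the thyroid hormone carrier Ttr by -0.30 ± 0.17. Ttr read 13.6 on controls and 13.3 on the arrays labelled Fmr1 KO, near the highest value of any probe set, 13.9. The erythroid list was not tested, and its measured members Bpgm and Slc4a1 differed by 0.14 ± 0.12 (SE) and -0.04 ± 0.14.

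Stress lists had lower medians, though none of their calls held with an estimated correlation. Of 34 genes of the dissociation and immediate early response, 30 had a lower mean, with a median of -0.38 (camera adjusted p = 2.28e-05; adjusted p = 0.524 with an estimated correlation). The immediate early gene Junb differed by -0.74 ± 0.34 (SE), Ier3 by -0.56 ± 0.22, Klf6 by -0.49 ± 0.23 and Fosl2 by -0.23 ± 0.10. This median was -0.18 without KO-labelled array 2. Of 31 genes of the unfolded protein and oxidative stress response, 24 had a lower mean, with a median of -0.13 (camera adjusted p = 0.00271; adjusted p = 0.524 with an estimated correlation), among them the peroxidase Gpx1 at -0.48 ± 0.14 (SE), the stress transcription factor Atf4 at -0.36 ± 0.11 and Herpud1 at -0.39 ± 0.16, while the metallothionein Mt1 differed by 0.32 ± 0.13. Of 29 interferon response genes, 24 had a lower mean, with a median of -0.12 (camera adjusted p = 0.0171; adjusted p = 0.735 with an estimated correlation). The antigen presentation genes B2m and Psmb8 differed by -0.50 ± 0.24 (SE) and -0.33 ± 0.13, Igtp by -0.38 ± 0.16 and Ifi27 by -0.29 ± 0.15. The interferon call ended without control array 5 (median -0.01, camera adjusted p = 0.950) or KO-labelled array 2 (-0.07, 0.241), while the median was -0.20 without control array 1, and the unfolded protein call without KO-labelled array 5 (0.0641). The dissociation list mean was 8.31 and 8.04 on KO-labelled arrays 1 and 2 and 8.49 on control array 1, the arrays with the lowest microglia marker means, and 8.77 to 9.36 on the others. The unfolded protein mean was lowest, 8.40, on KO-labelled array 5.

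Circadian clock genes, 12 higher and 7 lower with a median of 0.22, were called (camera adjusted p = 0.00896; adjusted p = 0.647 with an estimated correlation). The nuclear receptor Rorb differed by 0.77 ± 0.30 (SE), Per3 by 0.39 ± 0.17, Arntl by 0.32 ± 0.16 and Hlf by 0.26 ± 0.13. The list mean was 8.41 on control array 1 and 8.67 and 8.90 on KO-labelled arrays 1 and 2, the arrays with the lowest microglia marker means, and 8.07 to 8.28 on the other arrays. With the microglia marker mean as a covariate the median was -0.03 (camera adjusted p = 0.661). The call ended without control array 2 (camera adjusted p = 0.0588), without control arrays 2 and 3 (0.148) and without KO-labelled array 2, where the median was 0.01 (0.175). It also ended with array weights (median 0.09, 0.135) and without control array 1 and KO-labelled arrays 1 and 2, where the median turned to -0.03 (0.466). The remaining lists were not called with all arrays. They were glucocorticoid response genes, 5 higher and 11 lower (camera adjusted p = 0.762), reactive astrocyte genes, 17 higher and 17 lower (0.838), and cell cycle genes, 8 higher and 20 lower (0.0896). The kinase gene Sgk1 differed by -0.63 ± 0.24 (SE), Sult1a1 by -0.30 ± 0.14, Nfkbia by -0.38 ± 0.22 and Mt2 by 0.34 ± 0.20, and the glucocorticoid list was called lower without control array 1 and KO-labelled arrays 1 and 2 (median -0.16, camera adjusted p = 0.0370). Serpina3n differed by 0.37 ± 0.13, Cd14 by -0.58 ± 0.27 and H2-T23 by -0.40 ± 0.19. In the cell cycle list Pcna differed by -0.48 ± 0.19, Ccnd1 by -0.39 ± 0.16, Mcm6 by -0.20 ± 0.08 and Top2a, a low signal at 5.82 on controls, by -0.17 ± 0.09.

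Over all lists, camera called 16 of 30, 11 higher and 5 lower, and 0 held with an estimated correlation, where the smallest adjusted p was 0.524. Fry called 0 (smallest adjusted p = 0.322), and the exact permutation test called 0 after adjustment, with the FMRP ligand and endothelial lists at an unadjusted exact p under 0.05. Array weights ended the lipid call (median 0.08, camera adjusted p = 0.0750). Leaving out control array 1 and KO-labelled arrays 1 and 2 ended the lipid call (0.04, 0.342) and the calcium call (0.04, 0.156). Xist signal as a covariate ended the glutamate, calcium, cholesterol, lipid and circadian calls (0.0831 to 0.428). With the microglia marker mean of each array as a covariate, an alternative added after the data were seen, camera called 5 lists: FMRP ligands higher, and endothelial, unfolded protein, oxidative phosphorylation and cholesterol genes lower, the last against its direction without the covariate. In that fit the astrocyte identity list had a median of -0.03 (camera adjusted p = 0.989, in a range of 4.9e-17 to 0.989 over its alternatives), and the calls for the other astrocyte function lists and for the dissociation, interferon and circadian lists ended.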

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

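The tests of explanations in this part were chosen after the results were seen. Among 350 groups of 5 arrays examined for the named genes and list means, 10 held 1 array far from the others, where chance gives about 18. The measure is the gap between that array and its nearest neighbour as a share of the group's whole range.

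Control array 1 stood apart in 5 of them. Its microglia and macrophage mean of 9.33, against 10.0 to 10.2 on the other controls, gave a share of 0.792. Tmem119 read 8.25 there against 9.17 to 9.43 (share 0.778), and Tyrobp 8.70 against 9.55 to 9.86 (0.728). Slc4a4 read 10.9 against 10.2 to 10.4 (0.715), and Sgk1 8.55 against 9.38 to 9.71 (0.716). In the other control groups, Cnbd2 read 7.96 on array 5 against 8.49 to 8.60 (share 0.831), and Cd99l2 read 6.84 on array 2 against 7.29 to 7.40 (0.799). Among the arrays labelled Fmr1 KO, Ptprb read 6.41 on array 1 against 6.05 to 6.15 (share 0.720), the mural and fibroblast mean was 7.26 on array 1 against 6.95 to 7.04 (0.722), and Top2a read 5.43 on array 4 against 5.68 to 5.78 (0.718).

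Astrocyte genes had higher and microglia markers lower means in the arrays labelled Fmr1 KO. Neither list held with an estimated correlation, fry or the exact permutation test after adjustment. KO-labelled arrays 3 to 5 lay within the control range of both list means. For the microglia mean this rested on control array 1 at 9.33. The other controls, at 10.0 to 10.2, all lay above KO-labelled arrays 3 to 5, at 9.67 to 9.90. A candidate explanation for these means is a different share of microglial RNA between arrays, although the EGFP gate would be expected to remove microglia. The microglia list's most abundant genes were read on every array: Selplg read 12.6 ± 0.44 (SD, n = 5) on controls and 12.1 ± 0.53 on the arrays labelled Fmr1 KO, and Csf1r, Ctss, C1qb and P2ry12 differed by -0.47, -0.54, -0.47 and -0.49. With the microglia mean as a covariate, the difference of the astrocyte list mean went from 0.369 to -0.0153 (95% interval -0.371 to 0.340), the value this explanation needs, though an astrocyte change that sets both shares would give it too. Without the Xist-positive control arrays the difference was 0.279 (95% interval -0.514 to 1.07), too wide to weigh their part. An effect of genotype on the cells' makeup or on astrocyte genes stays open, and is not shown by these tests.

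The Fmr1 signal was not lower in the arrays labelled Fmr1 KO. A swap of arrays between groups could not be weighed: the lowest Fmr1 signal lay -0.564 log2 units from the median of all arrays, on control array 2, so the probe set marked no array as a knockout and could not reveal a swap. Probes that read transcript left in the knockout could give such a signal, and this cannot be told apart from other sources with 1 Fmr1 probe set and no stated site of disruption. A knockout allele that keeps its transcript stays open and was not tested.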

How the results depend on the processing

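The settings with a covariate, and those without the Xist-positive controls or without control 1 and KO-labelled arrays 1 and 2, were chosen after the data were seen. Genes past the adjusted threshold stayed at 0 in both directions under quantile normalization, equal medians, both other filters, averaged probe sets, trend and robust moderation, array weights, the 0.1 threshold and all probe sets, with 1064 to 1826 genes at an unadjusted p under 0.05 in limma for those that refit the genes. Without control 1 and KO-labelled arrays 1 and 2, 1 gene was higher, Tlcd1 at 2.06 ± 0.23 (SE; adjusted p = 0.0225), named after its value was seen. Leaving out each array gave 0 to 1 lower genes and 0 higher. An unadjusted p under 0.05 with a fold of at least 1.5 gave 67 higher and 47 lower genes, since that threshold has no adjustment. The Fmr1 difference was called under none of 23 alternatives and ran from -0.04 to 0.25 (adjusted p = 0.430 to 0.999). The 144 named genes had 3293 values under alternatives, of which 1 was called, and 42 changed sign, in 23 genes.

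Camera called 0 lists with an estimated correlation, which is all that this setting changes. Fry called 0 as well, and since it also asks another question than camera, the cause was not tested. The count was 5 with the microglia mean as a covariate and 7 with it and without the Xist-positive controls, 12 without those controls alone, and 13 to 17 leaving out each array. Of 750 list values, 91 lost a call and 24 gained one. Of all values 17 reversed in camera's direction, each with the microglia covariate, and 14 of these are among the lost calls and 1 among the gained. Values not called in either setting were not counted, nor were medians that turned while camera's direction held. Such medians were astrocyte identity (-0.0296) and potassium (-0.0376) with the covariate, and contact (-0.00056) with it and without the Xist-positive controls. The circadian median (-0.03) without control 1 and KO-labelled arrays 1 and 2 was another. With it the medians were -0.0222 for glutamate, -0.15 for cholesterol (adjusted p = 0.00369), 0.00346 for lipid, where only camera's direction turned, 0.0489 for interferon, 0.0893 for dissociation, -0.0253 for circadian and 0.0193 for microglia, the last by construction. Without the Xist-positive controls as well they were -0.0406 for astrocyte identity, -0.0871 for glutamate, -0.0307 for GABA, -0.0672 for potassium, -0.19 for cholesterol, -0.0573 for lipid, -0.18 for glycolysis, -0.00911 for interferon, where camera's direction was higher, -0.0565 for circadian and 0.00971 for microglia. The cause of the other reversals was not tested. With array weights, 9 called lists had medians closer to 0 by over 1.5 times, among them potassium (0.26), contact (0.20) and microglia (-0.34). Without control 1 and KO-labelled arrays 1 and 2, 12 did, the circadian one by turning to -0.03, among them astrocyte identity (0.16), potassium (0.10), contact (0.10), dissociation (-0.17) and microglia (-0.28). The FMRP ligand and endothelial lists were each called in 23 of 25 alternatives, all but estimated correlation and fry, with medians of 0.05 to 0.17 for the ligands (0.12 in the report) and -0.22 to -0.11 for endothelial markers. Those 23 all kept the preset correlation of 0.01, so they do not test that assumption. At an unadjusted p under 0.05, lower genes outnumbered higher ones without a dim filter (758 and 744) and with the replicate block (1074 and 1006). The same held without any 1 of control 1, 2 or 3 or KO-labelled 1, 2 or 3. It also held with array weights and under each setting chosen after the data were seen.

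The replicate numbers did not pair the arrays: correlations of same-numbered deviations were 0.53, -0.02, 0.19, 0.00 and 0.15, and not every array correlated best with its own number. With the replicate block 0 genes were higher and 0 lower, 2080 had an unadjusted p under 0.05 (1006 higher, 1074 lower), 16 lists were called, and Fmr1 differed by 0.19. The depth of signal over background is not given in the sources used here.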

Other observations

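The tests of the ribosomal protein genes were chosen after the results were seen, and the counts over other splits of the arrays before.

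Cytoplasmic ribosomal protein genes, a family picked because several stood among the smallest p-values, were lower in the arrays labelled Fmr1 KO. Of 62 measured, 56 had a lower mean, and 32 had an unadjusted p under 0.05, all lower. Of these, 22 passed adjusted over the family alone and 0 adjusted over all genes (limma). The family's mean log2 level was 7.57 ± 0.09 (SD, n = 5) in the arrays labelled Fmr1 KO and 7.83 ± 0.09 (SD, n = 5) in controls, a difference of -0.264 (95% interval -0.399 to -0.128). The KO-labelled arrays lay between 7.48 and 7.68 and the controls between 7.69 and 7.93, and the exact permutation p of 0.00794 is the smallest these assignments can give. The camera p was 0.00780 with an estimated correlation. This p, the exact p, the interval and the count adjusted over the family are all unadjusted for the choice of family from these same arrays. The median difference stayed below 0 under all 23 alternatives, the scalings included, from -0.33 to -0.15. Small nuclear and nucleolar RNA genes, 79 measured with 47 lower, gave a mean difference of -0.01 (exact permutation p = 0.976).

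Several explanations were weighed for the ribosomal difference. With a different share of microglial RNA as the whole cause, the difference should vanish under the microglia covariate, but it stayed at -0.192 (95% interval -0.318 to -0.0666). Without the Xist-positive control arrays it was -0.232 (95% interval -0.405 to -0.0576), with an exact permutation p of 0.0357, so the difference did not rest on these arrays alone. These values come from the arrays on which the family was picked, so they cannot exclude chance in that choice. A lower yield of short transcripts could lower such genes. The oxidative phosphorylation genes, also short, differed by -0.0608 (95% interval -0.368 to 0.247), an interval that holds both 0 and the ribosomal value. With the microglia covariate their median was -0.226 (camera at the preset correlation, adjusted p = 1.21e-13). Without the Xist-positive controls as well it was -0.257 (4.72e-14). These medians lie near the ribosomal values, so a lower yield cannot be told apart from an effect of genotype. Near-identical gene copies were not tested, and an effect of genotype on these mRNAs stays a hypothesis.

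KO-labelled arrays 1 and 2 shared high levels of some genes, named after their values were seen. Stoml3 read 7.80 and 7.88 there and 5.99 to 6.47 on the other 8 arrays, Scrg1 read 8.84 and 8.99 against 7.25 to 7.72, and Ncam2 read 8.88 and 8.84 against 7.27 to 7.82.

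Other splits of the 10 arrays into groups of 5 were fitted in the same way, with 100 drawn of 126. For genes past the adjusted threshold the real count was 0, so 100 of 100 splits gave as many by construction and the count decides nothing. Of these, 3 splits called any gene, and the highest other gave 634. For genes at an unadjusted p under 0.05, 20 of 100 gave as many as the real 1334. The other splits had a median of 521, and the highest gave 3788. For gene lists called, 18 of 100 gave as many as the real 16, and the highest other gave 19. The median over the other splits was 10 lists, so the set test at the preset correlation called many lists under arbitrary splits. Chance cannot be excluded for the unadjusted count or for the lists. Splits with several times the real count of genes point to a structure of the samples: the largest of them placed control 1 and KO-labelled arrays 1 and 2 in 1 group.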
